A study of Homo sapiens with 6 samples.

How the data were processed

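Messenger RNA was measured in 6 libraries of TC7 cells, a clone of the human colon carcinoma line Caco-2 that forms an enterocyte-like epithelium. The cells were left unchallenged (NI) or were challenged for 2 hours with Escherichia coli LF82 or Escherichia coli K12 at 10 bacteria per cell, each without or after 16 hours of pretreatment with 5 uM trichostatin A (TSA), an inhibitor of histone deacetylases. Stranded poly(A) libraries were sequenced, and each of the 6 conditions had 1 library. Groups were taken from the sample labels.

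The deposited values are linear ratios: for each gene and condition, the file gives a fold relative to the unchallenged, untreated library, which is 1 for every gene. TopHat2 2.0.11, featureCounts of the Subread package and DESeq 1.14 are named, with no role or order, per the submitters' processing notes, together with the builds hg19 and GRCh37. Whether any library pooled several cultures is not given in the sources used here. From the values themselves, the deposited ratios are (reads divided by a size factor + a constant) in a library over the same sum in the reference library. For all 23452 genes the ratios were solved by whole reads in every library within a tolerance of 0.001 reads, with a largest deviation of 5e-09 reads, and each gene had 1 solution in the first searched range that held one. The recovered constant was 5.01 normalised reads (median over the libraries), and the lowest gene in the files had a maximum over the libraries of 10.24 normalised reads, so that genes with few reads in every library were not analysed here. The recovery was tested on simulated reads of 2703 genes, and the reads of all 2703 were returned. Total recovered reads over the listed genes ranged from 48437060 to 72398911 per library. Reads without molecular identifiers are not independent molecules, so that the 95% Poisson intervals and the floor of 3 reads per library used here for a count of 0 cover counting error only.

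Tests were run on log2(normalised reads + 5), which equals the log2 of the deposited ratios plus each gene's level in the reference library. Recomputed and deposited log2 ratios differed by at most 1.7e-14. Folds are on this scale and understate the change of genes with few reads. Of the 23452 genes, the 22757 with a mean of at least 5 normalised reads were tested and 695 were left out. Limma 3.58.1 in R 4.3.3 was used with an intensity-dependent variance trend, without robust estimation, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The TSA effect, the challenge effect (mean of LF82 and K12 against NI) and the strain effect (LF82 against K12) came from 1 additive model of challenge and TSA. The interaction of TSA and challenge came from a model in which the 2 strains of a TSA state served as replicates of challenged cells. Both models leave 2 residual degrees of freedom. No condition was replicated, so the residual of the additive model is the non-additive part of the 6 libraries, the residual of the interaction model is the difference between strains, and the p-values measure the spread between these libraries only. Ratios of 2 single libraries have no replicate check and were described by size, with a minimum of 1 CPM in one of the libraries.

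The design fixed before the data were examined foresaw a count test with TMM scaling for counts, and log2(value + 1) for normalised values. The files held ratios. The negative binomial test planned for counts was not run on the recovered reads, where limma-voom served as an alternative. The constant of 5 that is part of the deposited ratios was kept in place of 1. This choice matters for 2 of the tests: with the constant of 1 the interaction test called 0 genes in place of 47, and the strain test 10 in place of 19. Results with a constant of 1 are therefore given beside those results.

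Also before the data were examined, 30 gene lists were fixed: antimicrobial peptides and proteins, inflammatory cytokines and chemokines, NF-kB targets and feedback regulators, immediate early genes, interferon-stimulated genes, pattern recognition receptors and adaptors, histone deacetylases, histone acetyltransferases and bromodomain proteins, replication-independent and polyadenylated histone genes, cell cycle inhibitors, cell cycle progression and DNA replication, apoptosis regulators, enterocyte differentiation markers, tight and adherens junctions, mucins and goblet cell markers, the CEACAM family, autophagy, the unfolded protein and integrated stress response, heat shock proteins, metallothioneins, oxidative stress response, cholesterol synthesis, hypoxia and glycolysis, neuronal and neuroendocrine genes, leukocyte, fibroblast and mesenchymal, and endothelial markers, housekeeping genes, mitochondrially encoded genes and ribosomal proteins. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 30 lists of a comparison. With an estimated correlation camera refers its statistic to the 2 residual degrees of freedom, so few lists could pass. A list that does not pass there is therefore not shown to owe its camera call to correlation between members. Fry asks whether a list changed at all, not whether it changed more than other genes. For single pairs of libraries, the median of a list was placed among 10000 random lists of the same size matched on mean expression. Per tested comparison, the 10 called genes with the largest rise and the 10 with the largest fall are named. They had at least 1 CPM on average over the libraries, a gene symbol and, for TSA, the same sign in the 3 challenge conditions. Called genes with a lower average were not named by this rule, whatever the size of their change. Uncharacterised, antisense and small RNA symbols are skipped. Members of the antimicrobial, cytokine and NF-kB lists, HDAC1 to HDAC11 and CDKN1A may always be named, and of any other list up to 4 called members with the largest change and up to 2 others. Some genes that this rule takes are not reported here. Per single pair, the 5 largest rises and 5 largest falls with at least 50 normalised reads in one library may be named.

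Alternatives were quantile normalisation, no filter, a mean of at least 25 normalised reads, limma-voom on the recovered reads, constants of 0.1 and 1, a fold of at least 2, TSA without the challenge term, each strain alone, and each library (for TSA, each challenge condition) left out in turn. For single pairs they were constants of 0.5 and 2, total-read scaling and a minimum of 5 CPM. Total-read scaling, tests on the deposited ratios alone, reads thinned to the lowest library total (48437060), and list tests under other scalings or with a constant of 1 were added after the data were seen. In simulated counts with a dispersion of 0.005, the TSA test recovered 67.2%, 83.6% and 95.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 9 false calls among 22682 genes. The challenge test recovered 56.7%, 73.1% and 90.9% with 6 false calls among 22676 genes, the interaction test 10.4%, 62.7% and 83.3% with 3 among 22710, and the strain test 56.7%, 73.1% and 90.9% with 10 among 22690. For each test only 67, 67 and 66 genes were changed at these folds. In the data 76.7% of genes were called for TSA, so the simulated rates need not hold there. The median SE in the data was 0.165 for challenge, 0.302 for the interaction and 0.191 for strain, on the log2 scale. The simulated rates rest on the dispersion of 0.005 and need not hold for these tests either.

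Symbols and Ensembl identifiers are those of the files, where 56 symbols occur more than once. Positions are not given because the annotation at hand is of another genome build; it was used only for gene biotypes, matched by identifier. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.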

Results

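Messenger RNA of TC7 cells, an enterocyte-like clone of the colon carcinoma line Caco-2, was sequenced in 6 conditions with 1 library each. Unchallenged cells (NI) and cells challenged for 2 hours with E. coli LF82, a strain of the adherent-invasive type, or with the laboratory strain E. coli K12 were each studied without and with pretreatment by 5 uM trichostatin A (TSA), an inhibitor of histone deacetylases, for 16 hours. Total recovered reads were 72398911 for NI, 49058896 for NI with TSA, 48437060 for LF82, 52422725 for LF82 with TSA, 68977828 for K12 and 61173090 for K12 with TSA. Levels are given as reads divided by the library's size factor (normalised reads). The labels give no batch and do not say whether the K12 libraries were prepared or sequenced with the others. A batch could therefore coincide with the comparison of strains. Because no condition was replicated, every test used the agreement between conditions as its error, with 2 residual degrees of freedom. P-values are those of limma with Benjamini-Hochberg adjustment unless stated otherwise.

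The first comparison asked what TSA changed in these epithelial cells, as a mean over the 3 challenge conditions. Of the listed genes, 20 of 24 neuronal and neuroendocrine, 24 of 31 interferon-stimulated, 15 of 19 histone and 7 of 7 metallothionein genes rose, and 22 of 33 enterocyte, 25 of 29 junction and 5 of 7 CEACAM genes fell. These lists passed a test against other genes (camera), and none passed it with an estimated correlation (adjusted p = 0.386 to adjusted p = 0.637). That form rests on the 2 residual degrees of freedom, so few lists could pass it. The estimate was below the preset 0.01 for neuronal (-0.03), interferon-stimulated (-0.014), histone (-0.031) and junction genes (-0.025). It was above the preset for enterocyte (0.042), metallothionein (0.497) and CEACAM genes (0.525). The neuronal kinesin gene KIF5C (ENSG00000168280.12) had 8.08, 6.40 and 13.3 normalised reads without TSA (NI, LF82 and K12) and 5571, 6142 and 6106 with TSA, a log2 change of 8.73 ± 0.15 (SE; adjusted p = 4.8e-11). The pore-forming tight junction claudin CLDN2 (ENSG00000165376.6) had 18510, 19870 and 22390 normalised reads without TSA and 228.2, 410.8 and 659.8 with TSA, and fell by 5.65 on the log2 scale (SE 0.17; adjusted p = 7.5e-10).

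Of 22757 genes tested, 17456 (76.7%) were called between TSA and no TSA, 9516 higher and 7940 lower, and 6433 of the rises and 3704 of the falls were at least 2-fold. After KIF5C the largest rises were those of SYT11, a synaptotagmin (log2 change 8.37), the nerve growth factor receptor NGFR (8.26), the adipocyte fatty acid-binding protein FABP4 (8.14), the alpha-tubulin TUBA1A (8.10), ZCCHC12 (7.86), HPCAL4 (7.81), the autophagy-related GTPase IRGM (7.70), TMEM59L (7.67) and beta-synuclein SNCB (7.58). FABP4 had no read in the LF82 and K12 libraries, so that it was at least 429-fold higher with TSA under LF82 and at least 666-fold higher under K12, against a floor of 3 reads per library. After CLDN2 the largest falls were those of the cytochrome CYP2W1 (-5.59), the membrane mucin MUC17 (-5.35), the fructose transporter SLC2A5 (-5.03), UNC13C (-4.97), LHFPL3 (-4.93), the intestinal fatty acid-binding protein FABP2 (-4.89), the intestinal surface antigen GPA33 (-4.82), the kinase AATK (-4.59) and the annexin ANXA13 (-4.59). All 20 genes kept their call and direction in every alternative run. Tubulin genes share sequence, so TUBA1A is uncertain to the extent that reads could be assigned to a paralog.

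Of 24 tested neuronal and neuroendocrine genes 20 rose, 3 fell and 1 was not called, with a median log2 change of 2.47 (adjusted p = 8.75e-05 against other genes, camera; adjusted p = 0.386 with an estimated correlation). Besides SYT11, the adhesion molecule NCAM1 rose by 6.68, the granule protein CHGB by 5.18 and the synaptic vesicle protein SYP by 5.16. Of 31 interferon-stimulated genes 24 rose and 2 fell (median 1.53, adjusted p = 0.000172; adjusted p = 0.386 with an estimated correlation), led by IFIT1 (6.68), IFI6 (5.65), the immunoproteasome subunit PSMB9 (4.86) and IFIT2 (4.48), whereas OAS1 changed by 0.04 (adjusted p = 0.81). Of 19 histone genes that are made outside S phase or polyadenylated, 15 rose and 4 fell (median 1.52, adjusted p = 0.0024; adjusted p = 0.386 with an estimated correlation), with HIST1H1C at 3.03 and HIST1H2BC at 3.0. All 7 metallothionein genes rose (median 3.12, adjusted p = 0.0024; adjusted p = 0.585 with an estimated correlation), with the zinc-binding MT2A at 4.33 and MT1X at 3.69. Histone and metallothionein genes are families with similar sequences, so single members are uncertain.

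Of 33 enterocyte markers 22 fell, 6 rose and 5 were not called (median -1.23, adjusted p = 0.00037; adjusted p = 0.443 with an estimated correlation). The peptide transporter SLC15A1 fell by 3.36 and MTTP, which loads lipid onto apolipoprotein B, fell by 3.17, whereas the brush border enzyme MGAM rose by 2.84. Of 29 tight and adherens junction genes 25 fell and 2 rose (median -0.69, adjusted p = 1.96e-05; adjusted p = 0.386 with an estimated correlation). CLDN15 fell by 2.09 and MARVELD3 by 1.91, while F11R, which is listed under 2 identifiers, stood at -0.18 (adjusted p = 0.61) under one of them. Of 7 CEACAM genes 5 fell and 1 rose (median -2.23, adjusted p = 0.0261; adjusted p = 0.637 with an estimated correlation). CEACAM1 fell by 2.75 and CEACAM7 by 2.44, and CEACAM21 rose by 2.39; these paralogs share sequence and are uncertain. Of 20 mucin and goblet cell genes 10 fell and 6 rose (adjusted p = 0.146), among them CLCA1 at 4.96 and ZG16 at -3.32.

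Markers of cell types that a clonal line should not hold moved with TSA as well. Of 21 fibroblast and mesenchymal markers 18 rose and 2 fell (median 1.87, adjusted p = 0.000981; adjusted p = 0.386 with an estimated correlation), with VIM at 4.84, COL6A3 at 4.50 and ZEB1 at 3.27. Of 8 endothelial markers 7 rose (median 1.53, adjusted p = 0.0264; adjusted p = 0.443 with an estimated correlation), and of 16 leukocyte markers 11 rose and 3 fell (median 1.19, adjusted p = 0.133), with CORO1A at 5.58. Under quantile normalisation the endothelial median was 0.95 with 5 rises (adjusted p = 0.0835) and the leukocyte median 0.46 with 6 rises and 3 falls. The share of mitochondrially encoded reads was 6.24%, 5.59% and 5.75% with TSA and 5.14%, 4.63% and 4.78% without, and the 10 most abundant genes took 7.15% to 7.43% of reads with TSA and 5.22% to 5.43% without.

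The histone deacetylase genes changed in both directions, 9 up and 9 down of 18 (median 0.01, mean 0.25, adjusted p = 0.963). HDAC9 (3.31), HDAC3 (1.28), HDAC5 (1.23), HDAC11 (0.96), HDAC4 (0.48) and HDAC6 (0.27) rose, and HDAC7 (-2.27), HDAC10 (-1.52), HDAC2 (-0.93), HDAC8 (-0.33) and HDAC1 (-0.24) fell. Of 20 histone acetyltransferase and bromodomain genes 12 fell and 5 rose (13 and 5 adjusted over the list alone; median -0.65, adjusted p = 0.0264; adjusted p = 0.443 with an estimated correlation), with the coactivator NCOA2 at -2.20 and BRD1 at -2.03. Of 36 cell cycle progression and replication genes 24 fell and 7 rose (median -0.41, adjusted p = 0.00415; adjusted p = 0.645 with an estimated correlation), but the median was -0.15 with 17 falls under quantile normalisation (adjusted p = 0.399) and -0.26 with 21 under total-read scaling. Among them were cyclin D1 (CCND1) at -3.20, TYMS at -2.50 and CDK4 at -2.11, against TK1 at 1.71. Of 16 entries for cell cycle inhibitors 9 rose and 4 fell (10 and 4 adjusted over the list alone; adjusted p = 0.146), with CDKN2D at 3.04 and CDKN1A, which encodes p21, at 0.42 ± 0.12 (adjusted p = 0.0088).

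Antimicrobial and inflammatory genes changed in both directions with TSA. Of 20 antimicrobial genes 10 rose, 8 fell and 2 were not called. The protease inhibitor WFDC2 rose by 3.86, DEFB4A by 3.18, PGLYRP4 by 3.09 and PGLYRP2 by 2.34. The values of PGLYRP2 and DEFB4A come from the challenged libraries: in unchallenged cells PGLYRP2 went from 63.8 to 38.9 normalised reads with TSA, and DEFB4A had 0 reads without and 1 read with TSA. REG4 fell by 2.5, PLA2G2A by 1.73, the defensin DEFB1 by 1.32 and lysozyme (LYZ) by 1.32, and PI3 stood at -0.29 (adjusted p = 0.15). The list's median was 0.44 and its mean 0.50, while the test against other genes pointed down (adjusted p = 0.757), and in the pair of unchallenged libraries the median was -0.28. Of 33 cytokine and chemokine genes 18 rose and 8 fell (median 0.74, adjusted p = 0.226), from CXCL10 (5.30) and CXCL11 (4.26) to TNFSF10 (-1.63) and TNFSF15 (-1.67). Of 30 NF-kB targets and regulators 8 rose and 16 fell (median -0.31, adjusted p = 0.142), with BIRC3 at 2.12, TRAF1 at 1.84, BCL3 at -2.19 and BCL2L1 at -1.66. Of 37 immediate early genes 19 rose and 11 fell (adjusted p = 0.283), with CTGF at 4.59 and FOSL1 at -2.93, and of 32 pattern recognition receptors and adaptors 16 rose and 12 fell (adjusted p = 0.963), with TLR6 at 4.27, TLR10 at 3.45, TLR1 at 3.20 and NLRC5 at 2.57. For every list without a second count, the counts adjusted over the list alone equalled those over all genes, except for ribosomal proteins.

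The 3 challenge conditions gave similar TSA changes. Across the 22757 genes, log2 ratios of pairs that share no library correlated at r = 0.93 (NI with LF82), 0.93 (NI with K12) and 0.95 (LF82 with K12), with Spearman values of 0.92, 0.92 and 0.94, where genes are not independent replicates. For the genes changed by TSA, the median log2 change of all tested genes was 0.113 with the authors' scaling, 0.255 with total-read scaling and -0.096 with quantile normalisation, and the rises and falls called were split 9516 to 7940, 10504 to 6937 and 7960 to 9364. Changes are given as fitted, without subtraction of these medians. Under quantile normalisation 1 or 2 called members of a list had the other sign in 15 lists, neuronal, junction and cell cycle genes among them, and 5 antimicrobial genes rose and 8 fell. The test of histone acetyltransferase and bromodomain genes no longer passed there (adjusted p = 0.492, and 0.057 with total-read scaling). Immediate early genes (adjusted p = 0.0184; 0.561 with an estimated correlation), cell cycle inhibitors (0.0192; 0.436) and autophagy genes (0.00865; 0.492) passed under quantile normalisation and not under the other scalings. The median of pattern recognition receptors and adaptors went from 0.53 to 0.04. In the reported tests no list call held with an estimated correlation, where the lowest adjusted p was 0.386.

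**Figure D1:**
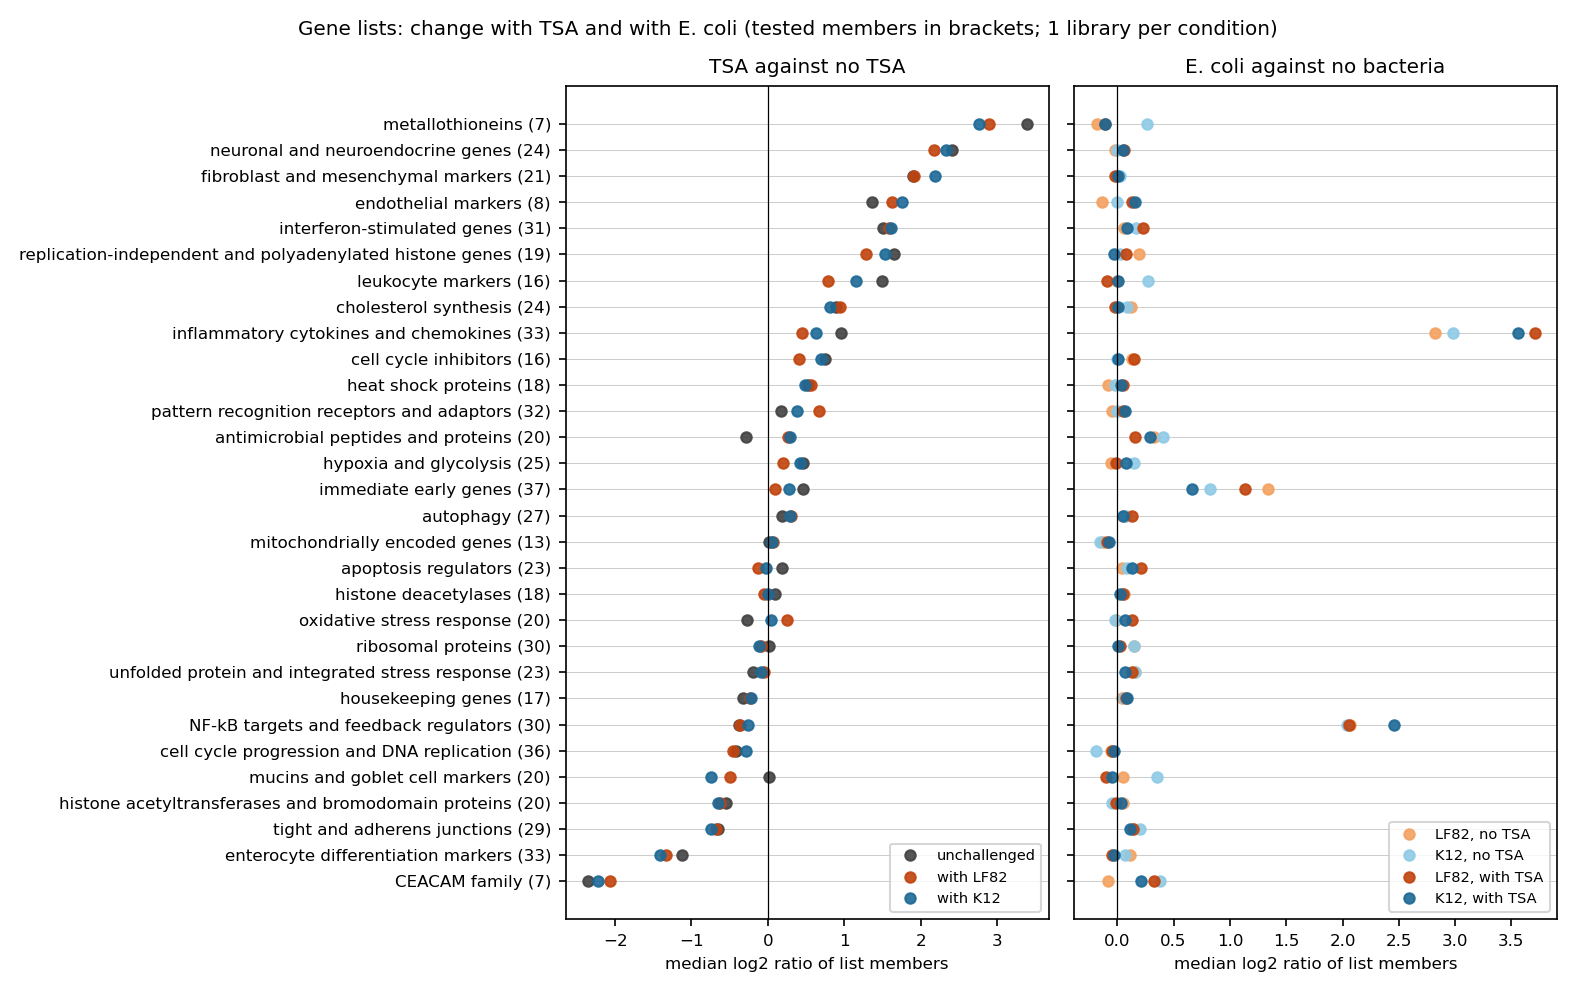
Median log2 ratio (x axis) of the tested members of 30 gene lists (y axis, number of members in brackets), with 1 point per pair of libraries, for TSA against no TSA (left) and E. coli against no bacteria (right). Neuronal genes lie above 2 and CEACAM genes below -2 in the 3 TSA pairs, and cytokine and NF-kB genes lie above 2 in the 4 challenge pairs.

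The second comparison asked what a 2 hour challenge with E. coli changed, over both strains and both TSA states. Of the listed genes, 26 of 33 cytokine and chemokine genes, 25 of 30 NF-kB targets and regulators and 30 of 37 immediate early genes rose. These lists passed camera, but not with an estimated correlation (adjusted p = 0.104, adjusted p = 0.104 and adjusted p = 0.177). IL8 (ENSG00000169429.6), the neutrophil chemokine also named CXCL8, had 16.2 normalised reads in NI, 18570 with LF82 and 7524 with K12, and 96.8, 43970 and 15610 in the same conditions with TSA, a log2 change of 8.57 ± 0.19 (SE; adjusted p = 9.1e-10). Falls were fewer and smaller.

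Of 22757 genes 715 were called (3.1%), 642 higher and 73 lower, 358 of them at least 2-fold. The next largest rises were the chemokines CXCL1 (8.30), CCL20 (7.75), CXCL3 (7.29), CXCL2 (6.66), CCL2 (6.41), CXCL10 (6.37) and CXCL5 (5.93), the apoptosis inhibitor BIRC3 (7.04) and the interleukin IL1B (5.89). CXCL1, CXCL2 and CXCL3 are near-identical paralogs, and the split of reads between them is uncertain. Of 33 cytokine and chemokine genes 26 rose, 0 fell and 7 were not called (29 up and 1 down adjusted over the list alone; median 3.42, adjusted p = 1.91e-63; adjusted p = 0.104 with an estimated correlation). TNF rose by 5.88, IL1A by 5.46, CSF1 by 5.24, LTB by 4.94 and IL6 by 3.60, and TSLP stood at 0.57 (adjusted p = 0.47).

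Of 30 NF-kB targets and regulators 25 rose (29 adjusted over the list alone; median 2.31, adjusted p = 2.35e-67; adjusted p = 0.104 with an estimated correlation). Feedback inhibitors were among them, with TNFAIP3 at 4.70, NFKBIA at 4.53, ZC3H12A at 4.16 and NFKBIZ at 3.33, as were the adhesion molecule ICAM1 (3.87) and the heparan sulfate proteoglycan SDC4 (3.04). Of 37 immediate early genes 30 rose (34 adjusted over the list alone; median 1.02, adjusted p = 3.66e-53; adjusted p = 0.177 with an estimated correlation), led by DUSP5 (2.40), ZFP36 (2.35), KLF6 (2.22) and PHLDA1 (1.82).

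Of 20 antimicrobial genes 3 rose and 17 were not called (7 up adjusted over the list alone; median 0.22, mean 0.70, adjusted p = 7.9e-05; adjusted p = 0.195 with an estimated correlation). The elastase inhibitor PI3, elafin, rose by 3.40 ± 0.19 (adjusted p = 1.6e-06), from 3544 normalised reads in NI to 24550 with LF82 and 26240 with K12. Lipocalin LCN2 rose by 2.63 ± 0.29 (adjusted p = 0.00034) and SLPI by 0.59 ± 0.099 (adjusted p = 0.0072). DEFB1 (0.45, adjusted p = 0.21), LYZ (0.05, adjusted p = 0.94) and REG4 (-0.22, adjusted p = 0.67) were not called.

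Other lists had few calls. In tight and adherens junctions 5 of 29 genes rose (12 adjusted over the list alone; adjusted p = 1.26e-07; adjusted p = 0.177 with an estimated correlation), among them CTNNB1 (1.25) and CLDN4 (1.04). In the unfolded protein and integrated stress response 4 of 23 rose (7 adjusted over the list alone; adjusted p = 3.58e-07; adjusted p = 0.184 with an estimated correlation), led by PPP1R15A (1.41), and in apoptosis regulators 4 of 23 rose (7 adjusted over the list alone; adjusted p = 0.000182; adjusted p = 0.195 with an estimated correlation), led by the BH3-only genes BBC3 (3.30) and BIK (1.86). Of 31 interferon-stimulated genes 3 rose (6 adjusted over the list alone; adjusted p = 0.00681; adjusted p = 0.249 with an estimated correlation), and of 32 pattern recognition genes 3 rose (3 adjusted over the list alone; adjusted p = 0.33), with TLR7 at 3.18 and TICAM1 at 2.64. CDKN1A rose by 1.02 and HDAC9 by 1.81.

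The largest falls were those of PZP (-1.42), NME1-NME2 (-1.18), TFEC (-1.17), RASL11B (-1.16), KLHDC7A (-1.09), NHLRC1 (-1.0), PKDCC (-0.99), the forkhead factor FOXA1 (-0.96), the Wnt target AXIN2 (-0.91) and the nuclear receptor NR2F2 (-0.90). NME1-NME2 is a read-through gene that overlaps both of its parts and is uncertain. PZP lost its call without the NI library with TSA (-0.46, adjusted p = 0.25) or the LF82 library with TSA (-1.16, adjusted p = 0.087), NHLRC1 without the NI library with TSA (-0.92, adjusted p = 0.060) or the LF82 library (-0.97, adjusted p = 0.057), and AXIN2 without the NI library (-0.44, adjusted p = 0.22) or the LF82 library (-0.82, adjusted p = 0.082).

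Total-read scaling gave 617 calls, 479 higher and 138 lower, so that the share of rises was 77.6% against 89.8% with the authors' scaling. Without the NI library 1473 genes were called and without the NI library with TSA 1823, and a test on the ratios alone without a variance trend called 36.

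**Figure D2:**
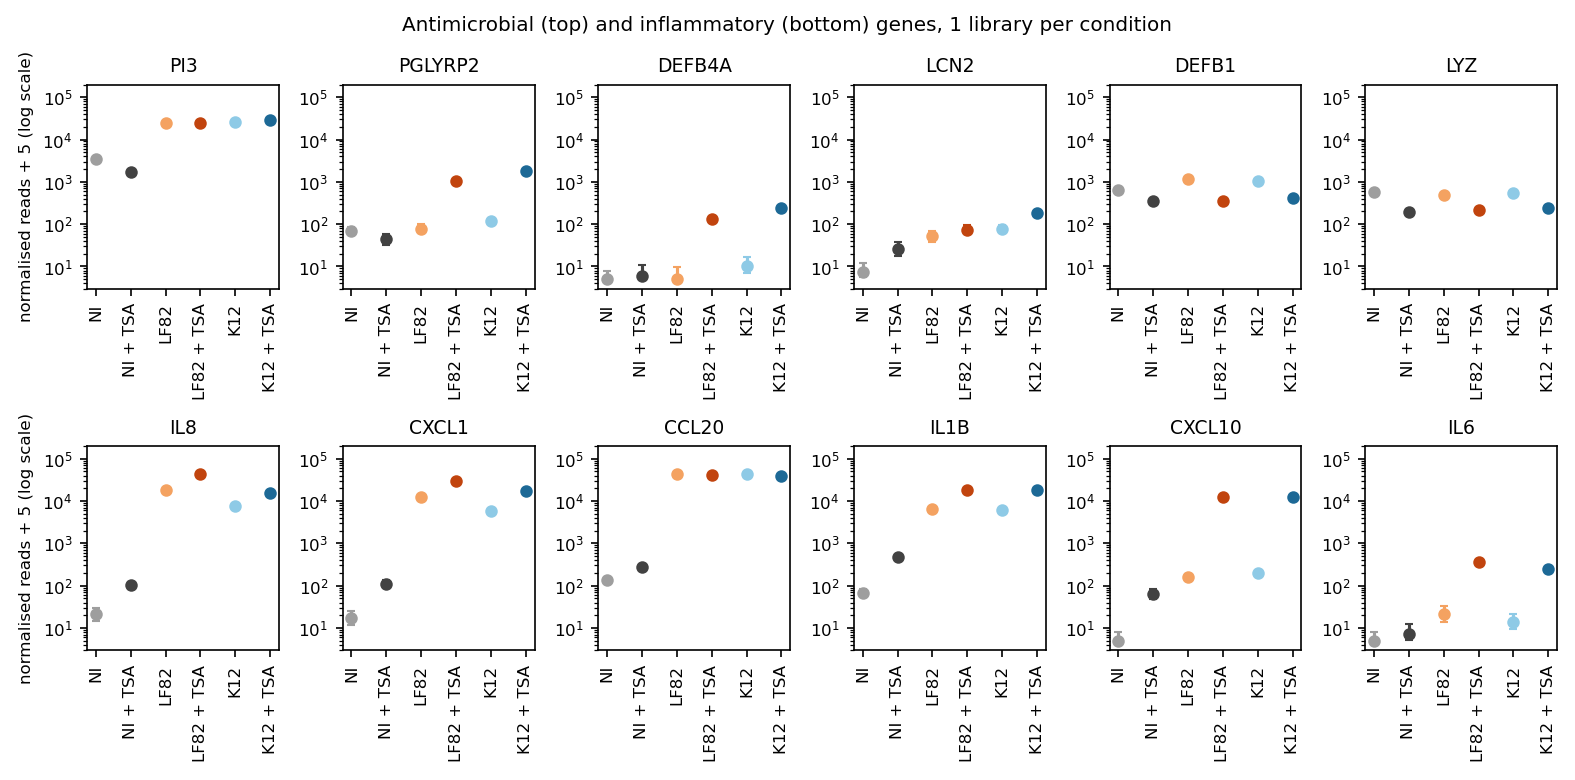
Normalised reads plus 5 (y axis, log scale) of 6 antimicrobial genes (top) and 6 inflammatory genes (bottom) in the 6 conditions (x axis), 1 library each, with bars for the 95% Poisson interval of the reads. PGLYRP2 and CXCL10 stand highest in the 2 challenged libraries with TSA, whereas CCL20 lies between 39760 and 43330 in the 4 challenged libraries.

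The third comparison asked whether TSA altered the response to bacteria. Few genes were called, none of them with the planned constant of 1, and the called ones differed in both directions. PGLYRP2, an amidase that cleaves bacterial peptidoglycan (ENSG00000161031.8), had 63.8 normalised reads in NI, 72.9 with LF82 and 114 with K12, and 38.9, 1044 and 1809 in the same conditions with TSA, an interaction of 4.49 ± 0.52 on the log2 scale (adjusted p = 0.028). CSF3, the granulocyte colony-stimulating factor, had 0, 827 and 311 normalised reads without TSA and 87.3, 250.4 and 201 with TSA, an interaction of -5.37 ± 0.70 (adjusted p = 0.043).

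The interaction was called for 47 of 22757 genes. At the constant of 5 the log2 change on challenge was higher with TSA for 27 and lower for 20, here called a larger and a smaller response. The sign alone does not tell a larger rise from a smaller fall. With the constant of 1 that had been planned before the data were examined, limma called 0 genes (2127 at an unadjusted p under 0.05). Larger responses with TSA were those of the pantetheinases VNN3 (4.80) and VNN1 (3.96), PGLYRP2, EGFL6 (4.12), MRPS24 (2.79), the ERK feedback inhibitor SPRY2 (2.10) and SALL4 (2.00). The chemokine CCL8 (3.99), the pentraxin PTX3 (3.23) and CXCL10 (2.44) were also called, but they had no read in NI, and with a constant of 0.1 their values were 0.27, -1.91 and -3.04, so that the constant sets their size or sign. VNN3 and CSF3 had no read in NI either, and kept their direction at 6.39 and -7.64 with a constant of 1 and at 8.20 and -10.95 with 0.1, so that their size also depends on it. Smaller responses were those of CSF3, ARRDC3 (-2.54), CSF1 (-1.76), NPTX1 (-1.52), RND1 (-1.48), the beta-tubulins TUBB2B (-1.40) and TUBB2A (-1.22), IL1B (-1.30) and SAT1 (-1.26). VNN3 had no read in the 2 unchallenged libraries and was at least 56.0-fold higher with LF82 and at least 56.5-fold higher with K12 in TSA-treated cells, against a floor of 3 reads per library. The pairs VNN1 and VNN3, and TUBB2A and TUBB2B, are paralogs and uncertain. A smaller response is not by itself a lower level with TSA. IL1B and RND1 were at a higher level with TSA in each challenge condition. IL1B stood at 17970 against 6448 normalised reads with LF82 and 18180 against 6072 with K12. BIRC3, which also had a smaller response, was higher with TSA as a mean over the challenge conditions. CCL20, another such gene, had 43330 (LF82) and 43190 (K12) normalised reads without TSA, and 40920 and 39760 with TSA. In unchallenged cells CCL20 had 134.1 without and 267.1 with TSA.

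Among antimicrobial genes PGLYRP2 and PI3 (1.13 ± 0.15, adjusted p = 0.041) were called, both with a larger response under TSA. PI3 was not called for TSA as a mean over the challenge conditions, so its larger response does not show a higher level with TSA. Of the 20 genes 18 were not called (3 up adjusted over the list alone, median -0.11, mean 0.38, adjusted p = 0.783). DEFB4A had 0, 0 and 6 reads without TSA (NI, LF82 and K12) and 1, 121 and 257 reads with TSA, an interaction of 4.36 ± 0.76 that was not called (adjusted p = 0.12), and its near-identical copy leaves its reads uncertain. Among cytokines and chemokines CSF3, CSF1, IL1B and CCL20 (-1.07 ± 0.10, adjusted p = 0.021) had a smaller response, CXCL10 was called at 2.44 with a sign that depends on the constant (-3.04 with 0.1, and -1.06 with limma-voom), and 28 of 33 were not called (6 up and 8 down adjusted over the list alone; median -0.31, mean -0.14, adjusted p = 0.125). With the planned constant of 1 that list passed camera (median -0.43, adjusted p = 7e-04; adjusted p = 0.925 with an estimated correlation), and with quantile normalisation its median was 0.12. IL6 stood at 3.61 (adjusted p = 0.088), IL8 at -1.12 (adjusted p = 0.70) and TNF at -0.84 (adjusted p = 0.68). Among NF-kB genes CFLAR (1.91) and RIPK2 (1.11) had a larger and BIRC3 (-1.12) a smaller response (5 up and 3 down adjusted over the list alone; adjusted p = 0.752). DUSP6, which dephosphorylates ERK, was called at 1.29 among the immediate early genes and CDKN1A at -0.74 among cell cycle inhibitors.

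Over the 33 cytokine and chemokine genes, the median log2 response to LF82 was 2.82 without TSA and 3.71 with TSA, and that to K12 was 2.98 and 3.56. With both strains 19 of them had a smaller response with TSA and 11 a larger one. For the 26 called higher on challenge the medians went the other way, from 4.96 to 4.83 with LF82 and from 4.75 to 4.62 with K12. Of these 26, 17 had a smaller and 9 a larger response with TSA for both strains, with a median interaction of -0.47. In challenged cells 13 of the 33 stood at least 2-fold higher and 4 at least 2-fold lower with TSA under both strains, and the same counts for the 20 antimicrobial genes were 6 and 6. Of the 642 genes called higher on challenge, 293 had a larger and 255 a smaller response with TSA for both strains, with a median interaction of 0.01.

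Lists called by camera for the interaction were ribosomal proteins (median -0.13, adjusted p = 7.23e-06), cholesterol synthesis (-0.13, adjusted p = 0.0162), mucins (-0.22, adjusted p = 0.0472), immediate early genes (-0.26, adjusted p = 0.0485) and leukocyte markers (-0.21, adjusted p = 0.0485), with adjusted p = 0.835 for ribosomal proteins and adjusted p = 0.90 for the others with an estimated correlation. The 47 calls depended on settings. With a constant of 1 limma called 0 genes (2127 at an unadjusted p under 0.05, against 2203 in the reported test), with 0.1 it also called 0 (2213), on the ratios alone 0 (2072), and with limma-voom 17. Without the LF82 library with TSA 0 genes were called (1454 at an unadjusted p under 0.05), without the K12 library with TSA 0 (1752), without LF82 194 and without K12 232. In the first 2 of these cases all 47 genes kept their direction and no value moved by more than 0.41. Selection of the calls by agreement between strains brings this about. The 2 unchallenged libraries could not be left out of this model. With limma-voom the interaction of CCL8 was 2.02 and that of PTX3 0.02. With a constant of 1 the leukocyte list no longer passed (adjusted p = 0.0507). With quantile normalisation and total-read scaling, camera no longer called immediate early genes (adjusted p = 0.184 and 0.0772), mucins (0.156 and 0.0771) or leukocyte markers (0.156 and 0.0772). Ribosomal proteins and cholesterol synthesis passed under both scalings.

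**Figure D3:**
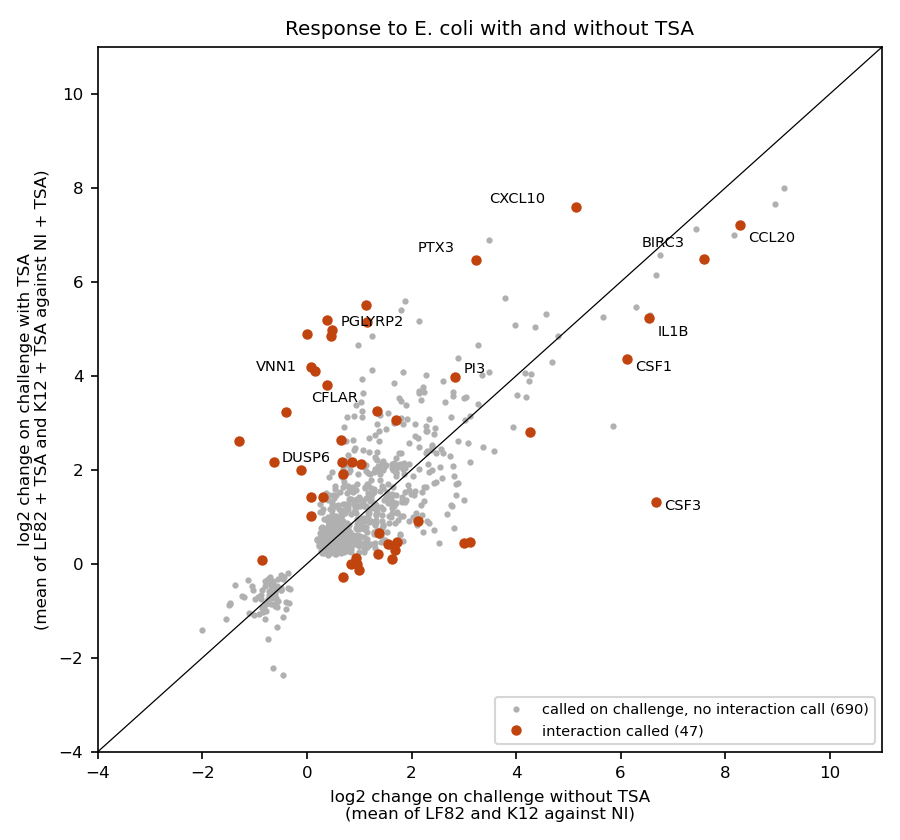
Log2 change on challenge without TSA (x axis) and with TSA (y axis), each the mean of both strains against unchallenged cells, for the 690 genes called on challenge with no interaction call (grey) and the 47 genes with an interaction call (red); the line marks equal change. Of the 47, 27 lie above the line and 20 below, and 25 of them were also called on challenge.

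The fourth comparison set LF82 against K12 within both TSA states. Called higher with LF82 were 5 of 37 immediate early genes, 2 of 33 cytokine and chemokine genes and 2 of 30 NF-kB genes. The immediate early list passed camera, but not with an estimated correlation (adjusted p = 0.378). The lipid droplet gene HILPDA had 1387 normalised reads with LF82 and 591 with K12 without TSA, and 2482 and 857 with TSA, a log2 difference of 1.38 ± 0.14 (SE; adjusted p = 0.0067). The transcription factor EGR1 had 32780 and 13000 normalised reads without TSA and 23160 and 12450 with TSA, a difference of 1.11 ± 0.11 (adjusted p = 0.0064).

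In all 19 genes were called, 17 higher and 2 lower with LF82, and 10 were called with the planned constant of 1. The other named genes higher with LF82 were IER3 (1.17), CXCL2, BTG2 (1.13), BHLHE40 (1.05), JUN (1.01), PIM3 (0.93), CXCL3 (0.92) and the growth factor EREG (0.91). CXCL2 had 15900 normalised reads with LF82 and 6479 with K12 without TSA, and 21710 and 10950 with TSA. The kinase gene MAST4 was lower (-0.95). Of 37 immediate early genes 5 were called, all higher with LF82 (14 adjusted over the list alone; median 0.27, adjusted p = 1.96e-22; adjusted p = 0.378 with an estimated correlation). Of 33 cytokine and chemokine genes 2 were called, both higher (7 up adjusted over the list alone; median 0.13, adjusted p = 0.00405; adjusted p = 0.378 with an estimated correlation), and IL8 stood at 1.40 (adjusted p = 0.071). Of 30 NF-kB genes IER3 and NFKBIZ (0.86) were called (3 up and 4 down adjusted over the list alone; adjusted p = 0.228). None of the 20 antimicrobial genes was called, over all genes or over the list alone (median -0.15, adjusted p = 0.228), where limma gave 1042 genes of 22757 an unadjusted p under 0.05. That count is below a share of 0.05, so over all genes small p-values were not in excess. The residual of this model also holds any TSA by challenge difference, which can raise the strain p-values. The count therefore does not show that strain differences are absent.

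Further lists called by camera were histone genes (median 0.22, adjusted p = 2.01e-07), mucins (-0.20, adjusted p = 1.24e-05), the CEACAM family (-0.25, adjusted p = 8.34e-05), cell cycle inhibitors (0.14, adjusted p = 0.00107) and hypoxia and glycolysis (-0.13, adjusted p = 0.00107), and with an estimated correlation adjusted p = 0.504 for CEACAM genes and adjusted p = 0.378 for the others. So were cell cycle progression genes (0.07, adjusted p = 0.00519; adjusted p = 0.771 with an estimated correlation), the unfolded protein and integrated stress response (0.09, adjusted p = 0.00889; 0.378), endothelial markers (-0.30, adjusted p = 0.0145; 0.378) and leukocyte markers (-0.10, adjusted p = 0.0333; 0.715). Cell cycle progression genes (adjusted p = 0.0926), endothelial (0.0501) and leukocyte markers (0.0943) did not pass camera under quantile normalisation, but passed with total-read scaling. The count of 19 depended on single libraries and was 5 without LF82, 33 without LF82 with TSA, 29 without K12, 36 without K12 with TSA, 369 without NI and 417 without NI with TSA. It was 10 with a constant of 1, 7 with quantile normalisation, 11 with total-read scaling and 0 in limma with a constant of 0.1 (791 at an unadjusted p under 0.05) and on the ratios alone (1199), against 32 with limma-voom. Without the LF82 library CXCL2, BTG2, BHLHE40, JUN, PIM3, CXCL3 and MAST4 were not called, with adjusted p from 0.082 (CXCL2) to 0.60 (MAST4), and without the LF82 library with TSA BTG2 (adjusted p = 0.060) and CXCL3 (adjusted p = 0.076) were not called.

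Single pairs of libraries were described by size, with no replicate check. At a minimum of 1 CPM, 3712 genes were at least 2-fold higher and 3287 at least 2-fold lower with TSA in unchallenged cells, 3799 and 3188 with LF82, and 3812 and 3112 with K12. LF82 against NI gave 311 and 48 genes and K12 against NI 332 and 50, and in TSA-treated cells LF82 gave 485 and 107 and K12 511 and 109. IL8 led the rises with LF82, at 878-fold without TSA and 432-fold with TSA, and was 356-fold higher with K12 without TSA, while CXCL10 led with K12 in TSA-treated cells at 194-fold. The largest falls on challenge without TSA were those of RASL11B with LF82 (log2 ratio -1.83) and AMER3 with K12 (-2.48), and with TSA those of PZP with LF82 (-2.27) and CLEC3A with K12 (-2.98). Crossed pairs that share no library, LF82 without TSA against K12 with TSA and the reverse, correlated across the 22757 genes at r = 0.38 and 0.39 (Spearman 0.17 and 0.13).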

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

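The tests of technical explanations in this part were chosen after the result was seen, except that of immediate early genes with thinned reads. Results with constants of 1 and 0.1, with limma-voom and with a library left out were planned, and total-read scaling and thinned reads were added after the data were seen. The difference between the response to E. coli with and without TSA was tested by an interaction term, and 47 genes passed. With the planned constant of 1 limma called 0 (2127 at an unadjusted p under 0.05), so within that test each call below rests on the constant of 5. Limma-voom on the recovered reads called 17 genes, all of them among the 47. The response was larger with TSA, on the log2 scale, for VNN3 (4.80), PGLYRP2 (4.49), EGFL6 (4.12), CCL8 (3.99), VNN1 (3.96), PTX3 (3.23), MRPS24 (2.79), CXCL10 (2.44), SPRY2 (2.10), SALL4 (2.0), CFLAR (1.91), DUSP6 (1.29), PI3 (1.13) and RIPK2 (1.11). With a constant of 0.1 the values of CCL8, PTX3 and CXCL10, which had no read in NI, were 0.27, -1.91 and -3.04, and those of VNN3 and CSF3, also without a read in NI, were 8.20 and -10.95 (6.39 and -7.64 with a constant of 1). The response was smaller with TSA for CSF3 (-5.37), ARRDC3 (-2.54), CSF1 (-1.76), NPTX1 (-1.52), RND1 (-1.48), TUBB2B (-1.40), IL1B (-1.30), SAT1 (-1.26), TUBB2A (-1.22), BIRC3 (-1.12), CCL20 (-1.07) and CDKN1A (-0.74). A larger or smaller response concerns the change on challenge and does not give the level with TSA in challenged cells. The 20 genes that the naming rule took for the interaction all lost their call without the LF82 library with TSA or without the K12 library with TSA, where limma called 0 genes (1454 and 1752 at an unadjusted p under 0.05). All 47 called genes kept their direction, and the median size went from 1.48 (median SE 0.18) to 1.48 (0.15) and 1.42 (0.15). No value moved by more than 0.41, while 1 residual degree of freedom was left in place of 2. This stability adds no support, because the residual of this model is the strain difference and called genes were thereby selected for agreement between strains. The NI library and the NI library with TSA enter every value and could not be left out.

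Interaction calls were weighed against the constant and read depth. Of the 14 called genes with under 50 normalised reads in some library, 5 kept their direction within 1 SE when the constant was 0.1 and 2 reversed, so their size may come from the constant. Of the 33 called genes with at least 50 normalised reads in every library, 33 kept direction and size. At that level the constant moves log2 values little, so the cutoff largely fixed this result and it adds no support. Their calls ended at median sizes of 1.22 before and 1.23 after, and SE of 0.13 and 0.13. The lowest adjusted p of limma became 0.068 with a constant of 1 and 0.19 with 0.1. The prior degrees of freedom of the variance fell from 5.64 to 4.36 and 3.06. With reads thinned to the lowest library total, 36 of the 47 genes were called in the same direction, which argues against depth. A difference between TSA states in the response stays open for the 33 genes, as a hypothesis from 1 library per condition.

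The breadth of the TSA response, 17456 of 22757 genes, was weighed against scaling, RNA of another cell type and the grouping of libraries. No common shift of all genes left fewer than 44.2% of them at least 2-fold away, a test added after the first scaling test was undecided, which argues against a single wrong factor per library. Under both other scalings 77.7% of all calls (13570 of 17456) and 86.6% of those of at least 2-fold (8774 of 10137) kept call and direction, the second short of the 90% set as the bound, so the part of the breadth that rests on scaling cannot be told apart from the rest. Fibroblast RNA would bring its abundant transcripts together, yet mean COL1A1 went from 2860 to 15300 normalised reads. The largest rise of COL1A2 (0.296 to 31.2), COL3A1 (26.1 to 249), DCN (2.1 to 23.9) and VIM (6.92 to 339) was 2.67% of that rise. Of these genes COL1A1, COL1A2, COL3A1 and DCN were chosen after their values were seen. COL1A1 was high without TSA where COL1A2 was near 0.296, so the low share concerns the COL1A1 rise only. It cannot exclude fibroblast RNA behind the smaller rises of the other genes. RNA of endothelial cells or leukocytes was not tested. Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave 17456 calls and the highest other gave 0, and 10 splits are too few for a share under 0.05.

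Values of immediate early genes were higher with LF82 than with K12 in 32 of 37 members in each TSA state, and 5 of the 37 were called (14 adjusted over the list alone, and 2 over all genes under quantile normalisation). The list test kept an adjusted p of 3.3e-21 with thinned reads (median 0.29) and of 1.6e-20 under quantile normalisation (0.27), which argues against depth and scaling, but in the reported test its adjusted p was 0.378 with an estimated correlation and 0.404 by fry. The LF82 library without TSA alone does not carry the list median. In TSA-treated cells that median of 0.23 lay at percentile 100 of random lists (-0.02 to 0.06), as did that of 0.39 without TSA (-0.02 to 0.08). Random lists do not hold the correlation between members (estimated at 0.146), so the percentile can overstate how unusual the median is. Several single calls, JUN and BTG2 among them, were lost without that LF82 library. A strain difference stays open as a hypothesis, as does any difference in handling, since strain and handling cannot be separated with 1 library per condition.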

How the results depend on the processing

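All 20 genes that the naming rule took for TSA kept call and direction in every alternative run, as did 9 of 20 for challenge, 0 of 20 for the interaction and 0 of 12 for strain. Over all settings, 817 values of named genes kept direction and side of the threshold, 220 lost their call and 3 reversed, and of the list tests 575 kept both, 91 were lost, 16 gained and 2 reversed. Total-read scaling, the ratios alone, thinned reads and list tests under other scalings or a constant of 1 were chosen after seeing the data, and unless stated the cause of a change was not tested. The genes changed by TSA numbered 17456, and 10137 with a fold of at least 2, which by construction lowers the count; with 1 challenge condition left out they numbered 16058 to 17451. The genes changed by E. coli challenge numbered 715, against 433 with a constant of 0.1, 358 with a fold of at least 2 and 36 on the ratios alone, and 641 to 1823 with a library left out (1473 without NI, 1823 without NI with TSA). The genes with a TSA by challenge interaction numbered 47, against 17 with limma-voom, and in limma 0 with a constant of 0.1, 0 with 1 and 0 on the ratios alone (2213, 2127 and 2072 at an unadjusted p under 0.05), and 0 to 232 with a library left out. The genes different between LF82 and K12 numbered 19, against 7 with quantile normalisation, 11 with a mean of at least 25 normalised reads, 32 with limma-voom, 0 with a constant of 0.1, 10 with 1, 7 with a fold of at least 2, 11 with total-read scaling, 0 on the ratios alone and 12 with thinned reads, and 5 to 417 with a library left out. With a constant of 0.1 the interaction reversed for PTX3 (-1.91) and CXCL10 (-3.04), and with limma-voom for CXCL10 (-1.06). Of the single condition pairs, a minimum of 5 CPM, which by construction leaves fewer genes, gave 238 genes for K12 against NI, and in TSA-treated cells 315 for LF82 and 337 for K12. By fry 26 of 30 TSA lists passed, among them antimicrobial genes (adjusted p = 0.0071, downward, against a median of 0.44) and cytokines (0.047, upward), against 6 of 30 for challenge, 0 for the interaction and 0 for strain. Fry does not compare a list with other genes, and 76.7% of tested genes were called for TSA. A pass by fry for TSA therefore does not set a list apart, and housekeeping genes passed as well (fry adjusted p = 0.0113). No list that passed camera for the interaction or strain passed fry (ribosomal proteins 0.314 for the interaction, immediate early genes 0.404 for strain). With an estimated correlation the challenge tests no longer passed (antimicrobial genes 0.20, cytokines 0.10). The cytokine list passed for the interaction with a constant of 1 (adjusted p = 7e-04; adjusted p = 0.925 with an estimated correlation). The cytokine median was 1.27 for TSA and 4.77 for challenge with a constant of 1, and the antimicrobial mean 0.70 for challenge. For the interaction the antimicrobial list had a mean of 0.38 and medians of -0.06 with quantile normalisation and -0.23 with a constant of 1, and the cytokine list a mean of -0.14 and medians of 0.12 with quantile normalisation, -0.43 with a constant of 1 and -0.28 with total-read scaling. Under quantile normalisation the challenge tests of housekeeping genes (adjusted p = 0.88) and ribosomal proteins (0.25) reversed. Planned negative binomial tests and their scalings were not run on the recovered reads, where limma-voom was. The TSA test compares libraries within a challenge condition, and without the challenge term 16830 genes were called. Genes with no read in some library are limited by depth, and their folds depend on the constant.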

Other observations

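Stress and metabolic genes changed with TSA in both directions. Of 24 cholesterol synthesis genes 18 rose and 5 fell (median log2 change 0.91, adjusted p = 0.0041, camera; adjusted p = 0.585 with an estimated correlation). The isomerase IDI1 rose by 2.16, from 17910 to 76240 normalised reads in unchallenged cells, INSIG1, which retains SREBP, by 2.01 and SREBF1 by 1.83. Of 18 heat shock genes 10 rose and 4 fell (adjusted p = 0.146), with HSPA2 at 4.55 and CRYAB at 2.74. Of 27 autophagy genes 13 rose and 6 fell (adjusted p = 0.203), with IRGM at 7.70, ULK2 at 2.09 and TFEB at -1.93. Of 25 hypoxia and glycolysis genes 13 rose and 9 fell (adjusted p = 0.606), with hexokinase HK1 at 5.54, the glucose transporter SLC2A1 at -3.85 and CA9 at -3.31. Of 20 oxidative stress genes 9 rose and 8 fell (adjusted p = 0.832), with TXNIP at 4.43 and GPX2 at -2.13. Of 23 apoptosis regulators 9 rose and 10 fell (median 0.03, mean -0.28, adjusted p = 0.521), with TNFRSF1A at -2.91 and XIAP at -2.13.

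Of 23 genes of the unfolded protein and integrated stress response 10 rose and 11 fell (adjusted p = 0.395), with XBP1 at -2.59, and the median was -0.13, but 0.19 with quantile normalisation and 0.03 with total-read scaling. Of 17 housekeeping genes 4 rose and 10 fell (median -0.19, adjusted p = 0.218), against 7 and 9 with quantile normalisation (median -0.14) and 6 and 8 with total-read scaling (median -0.03), with POLR2A at 1.15 and ACTB at -0.63. Of 13 mitochondrially encoded genes 2 rose and 2 fell (median 0.09, adjusted p = 0.624), but 2 rose and 5 fell with quantile normalisation (median -0.11) and 11 rose and 0 fell with total-read scaling (median 0.25), so the scaling decides these counts. Of 30 ribosomal protein genes 5 rose and 9 fell (4 and 9 adjusted over the list alone; median -0.07, adjusted p = 0.364), but 10 rose and 9 fell with quantile normalisation (median 0.05) and 12 rose and 3 fell with total-read scaling (median 0.09). On challenge, ribosomal protein genes had a median of 0.09 (adjusted p = 0.00171; adjusted p = 0.632 with an estimated correlation), but -0.04 with quantile normalisation and -0.01 with total-read scaling, and mitochondrially encoded genes -0.12 with 1 of 13 lower (4 adjusted over the list alone; adjusted p = 0.002; adjusted p = 0.249 with an estimated correlation). Cell cycle progression genes (median -0.09, adjusted p = 0.00358; 0.632 with an estimated correlation), autophagy (0.06, adjusted p = 0.00873; 0.405), housekeeping (0.07, adjusted p = 0.021; 0.32), oxidative stress (0.04, adjusted p = 0.026; 0.414) and hypoxia and glycolysis genes (0.03, adjusted p = 0.0373; 0.405) also passed camera on challenge, where the housekeeping, oxidative stress and hypoxia medians were -0.02, -0.02 and -0.07 with quantile normalisation and the autophagy median -0.03 with total-read scaling. With quantile normalisation and total-read scaling, camera no longer called autophagy (adjusted p = 0.284 and 0.174), housekeeping (0.876 and 0.577) or oxidative stress genes (0.513 and 0.311). Nor did it call hypoxia and glycolysis (0.733 and 0.499) or ribosomal protein genes (0.247 and 0.706). Cell cycle progression and mitochondrially encoded genes passed under both scalings.

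Both tests that follow were chosen before their results were seen. The first hypothesis was that genes at a low level without TSA rose and genes at a high level fell. Levels were set in the NI library, and changes were taken from the LF82 and K12 pairs, which do not share that library. In the 3991 genes with 11 to 50 normalised reads the median log2 change was 0.37 (LF82 pair) and 0.26 (K12 pair). In the 2763 genes with at least 5000 it was -0.53 and -0.53. The difference was 0.90 in the LF82 pair and 0.79 in the K12 pair, in the direction of the hypothesis, but the test cannot decide it. The NI, LF82 and K12 libraries are all without TSA, so genes low or high in NI are selected on their level without TSA. Any broad change unrelated to that level can then appear as a rise of low genes and a fall of high ones. The constant added to the reads also limits how far genes with few reads can fall. In the lowest bin 28.1% of genes were at least 2-fold higher in both pairs and 7.3% lower, against 3.1% and 28.0% in the highest. No read was found for 617 genes in the 3 libraries without TSA and for 9 in the 3 with TSA, and 30 of the 617 had at least 50 normalised reads in each library with TSA.

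The second hypothesis was that genes other than protein-coding ones are frequent among TSA rises, and it was not borne out. Among 6242 genes raised at least 2-fold, 33.9% were not protein-coding, below the 41.2% to 44.6% of 1000 random sets matched on mean expression. Among falls the share was 19.9%, above the 15.6% to 18.8% of the random sets. A biotype was found for 96.8% of tested genes.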
